A study of Mus musculus with 6 samples.

How the data were processed

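The series holds RNA sequencing of naive CD4+ T cells isolated from the spleen (3 libraries) and from the mLN (3 libraries) of untreated wild-type C57BL6/J mice. Per the labels' protocols, total RNA was extracted with RNAiso Plus and cleaned on a column, and libraries were made with a directional kit, NEBNext Ultra II. The molecule is given as polyadenylated RNA per the labels. How naive cells were sorted is not stated in the labels. Reads were processed with STAR and RSEM on mm10 per the submitters' processing notes, which state no versions. The annotation release and the strand setting of the counting are not given in the sources used here.

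The deposited expected counts are RSEM's estimated counts per gene, not normalized and not always whole, per the file headers. The deposited TPM values are transcript abundances scaled to a fixed total and the deposited FPKM values are fragments scaled by length and depth, both made by the authors from RSEM's effective lengths, per the file headers. The deposited transcript length and effective length per gene are in nucleotides per the file headers. The files each list 55487 Ensembl gene identifiers, of which 55141 were given a symbol from a reference of mouse gene names and 346 were not. A symbol shared by several identifiers stayed with the one of the highest count, and 107 further identifiers carry the identifier after the symbol. Coordinates, biotypes and transcript GC content were taken from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names. FPKM values were used only to look at their sums.

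Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr by group, which left 12486, and libraries were scaled by TMM factors. The main test was edgeR's two-sided quasi-likelihood F test with robust estimation and tissue as the only term, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are mLN minus spleen, and their standard errors are the size of the fold change over the square root of F. Means and standard deviations of CPM are over 3 libraries, scaled by total counts and TMM factors. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, the data.table package (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Each pair of replicates differed by more than sampling noise, with chi-square values per degree of freedom between 5.66 and 12.0, so no library was counted as a repeat of another.

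A total of 44 gene lists were fixed before the data were examined, covering T cell programs, markers of other cell types and signs of RNA quality. The 37 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry were run beside it. The genes named in the text follow a rule fixed at the same time. It takes the 12 called genes with the largest fold change in each direction among those with a mean of at least 5 CPM and no overlap between the groups, leaving out gene models without a name, pseudogenes and receptor or antibody segments. It adds up to 4 members of each list with the smallest p, and 12 checks of the sort and of the labels. Where another gene is named, it was chosen after its values were seen.

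Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2, limma-voom, limma on log2 of the deposited TPM plus 1, no filter and a stricter filter on low counts, the replicate number as a block, a threshold of 0.01, and each library left out in turn. Chosen after seeing the data were the removal of a smooth per-library trend of log2 CPM on transcript length or on GC content (loess span 0.3), the omission of mitochondrial, rRNA and ribosomal protein genes, the omission of markers of other cell types, and TPM values centred on each library's median.

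The gene test was tried on simulated data for this comparison of 3 and 3 libraries, with 12486 genes drawn from the real mean levels, estimated dispersions and library sizes. Of 50 genes changed at each size, the test recovered 28% at 1.3-fold, 60% at 1.5-fold, 60% at 2-fold and 94% at 4-fold, and it called 4 unchanged genes. It gave 125 calls in all, against 3699 in the real comparison. With so many fewer calls the adjusted threshold demands a smaller unadjusted p, so these shares need not hold for the real comparison. The list test called 5 of 5 lists of raised genes and 0 of 20 lists of unchanged genes. The raised lists held genes raised by 1.5-fold to 4-fold, and all genes were drawn independently. The simulation therefore does not test the list calls where genes of a list vary together or change less. A trend with length of 0.6 log2 units per 10-fold length was put into simulated mLN libraries and fell to 0.0411 after the correction, with 712 unchanged genes called before and 11 after it. The results for 3 of the differing genes are not reported here.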

Results

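Naive CD4+ T cells, which have left the thymus and have not yet met their antigen, circulate between lymphoid organs. The series set those taken directly from the spleen against those taken directly from the mesenteric lymph nodes (mLN), which drain the gut, in untreated wild-type C57BL6/J mice. Gene expression was measured by RNA sequencing of polyadenylated RNA in 3 spleen libraries and 3 mLN libraries. The expected counts summed to 14224966, 17862485 and 16218912 in spleen replicates 1, 2 and 3, and to 16139769, 13205499 and 20054205 in mLN replicates 1, 2 and 3. A floor of 3 counts per library corresponds to between 0.150 and 0.227 CPM (counts scaled to a common library total), for counting error only. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

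The comparison asks how the transcriptome of naive CD4+ T cells differs between the organs. Socs3, an inhibitor of cytokine signalling through STAT proteins, rose from 125 ± 9.33 CPM in spleen to 328 ± 20.1 CPM in mLN (SD, n = 3 each), a log2 fold change of 1.39 with a standard error of 0.0710. Bcl3, a nuclear partner of NF-kB, was 2.93-fold higher in mLN, and Spsb1, an adaptor of a ubiquitin ligase, was 2.61-fold higher. In the other direction, Il7r, the receptor chain for the survival cytokine IL-7, fell from 711 ± 48.9 to 404 ± 29.2 CPM (SD, n = 3 each). Of 12486 genes tested, 2010 were higher and 1689 lower in mLN at an adjusted p under 0.05 in edgeR's quasi-likelihood test, of which 58 and 197 changed by at least 2-fold. On the same counts with upper-quartile factors 1692 were higher and 2046 lower, or 45.3% higher against 54.3% with TMM factors. On the deposited TPM values the split was 2772 higher to 385 lower, or 87.8% higher, and the median log2 fold change of all tested genes was shifted to 0.21. With each library centred on its median, TPM gave 805 higher and 960 lower. Counts given below for log2 TPM include the shift.

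Socs3 (ENSMUSG00000053113), a protein-coding gene, lies on the minus strand of chromosome 11 between positions 117966079 and 117970047 of the mm10 genome, and its adjusted p was 6.88e-11. The other genes with the largest rises were Apol9b at 7.57-fold, the heat-inducible chaperone gene Hspa1b at 3.96-fold, Tspan9 at 3.35-fold, Dtx4, a regulator of Notch signalling, at 3.0-fold, Osgin1 at 2.96-fold, the interferon-induced antiviral gene Rsad2 at 2.63-fold, Acsbg1 at 2.45-fold and Rgs1, which dampens chemokine receptor signals, at 2.45-fold. Apol9b has a close copy, Apol9a, and Hspa1b a close copy, Hspa1a, so the division of reads within each pair is uncertain; Apol9a was 4.84-fold higher (adjusted p = 2.90e-05) and Hspa1a had an adjusted p of 0.329. The call of Rgs1 was lost on median-centred log2 TPM (adjusted p = 0.0770). Xntrpc, whose annotation overlaps Trpc2 so that its reads are uncertain, was 3.56-fold higher (adjusted p = 0.0312), and its call was lost without spleen replicate 2, mLN replicate 2 or mLN replicate 3, with adjusted p-values of 0.150, 0.0794 and 0.0648. It was also lost on median-centred log2 TPM (0.0749) and with the GC trend removed (0.0781). Its log2 fold change of 1.83 became 2.46 without spleen replicate 1. Several of these genes are weakly expressed, with mLN means of 16.8 CPM for Apol9b, 9.70 CPM for Hspa1b and 8.24 CPM for Osgin1.

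**Figure D1:**
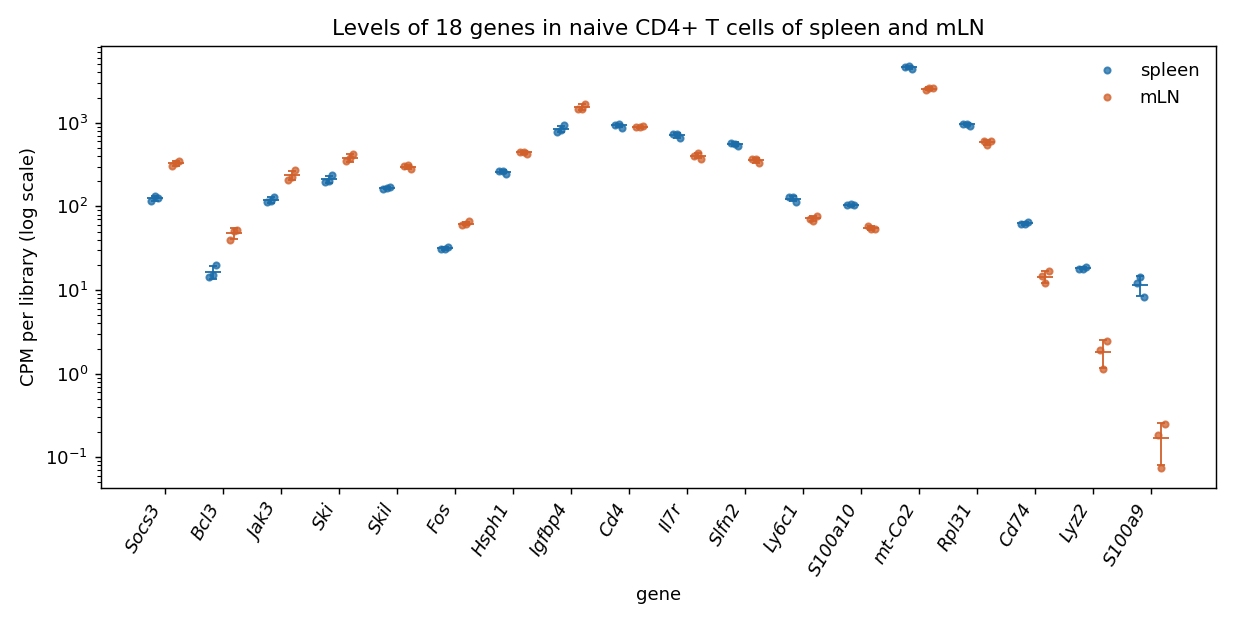
Expression in CPM (log axis) of 18 genes in each of the 3 spleen and 3 mLN libraries; points are libraries, horizontal marks are group means and bars are standard deviations. Socs3 lay near 125 CPM in spleen and 328 CPM in mLN, whereas Cd4 lay near 930 and 891 CPM.

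Genes of cytokine signalling moved in both directions. Of 16 tested members of the IL-7 and STAT5 signalling list, 9 rose and 2 fell (11 and 2 when adjusted over the list alone). Jak3, the kinase bound to the common cytokine receptor chain, rose 1.99-fold with a log2 standard error of 0.0864, while Il7r and the gene for the common chain itself, Il2rg, fell to 0.568 and 0.814 of their spleen levels. The Il2rg difference was 0.00164 on the log2 TPM scale. The list was higher in mLN by camera (adjusted p = 9.09e-04; adjusted p = 0.105 with an estimated correlation; 0.0683 after removal of the trend with GC content). In the cytokine receptor list 8 of 23 tested members rose, among them Tgfbr2 at 1.53-fold, Il21r at 1.5-fold and Il6ra at 1.42-fold, and 4 fell (8 and 4 when adjusted over the list alone; list adjusted p = 0.360).

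Transcripts of the TGF-beta response list were higher in mLN, with 10 of 19 tested members up and 0 down, and the same counts when adjusted over the list alone. Ski and Skil, which encode repressors of SMAD transcription factors, rose 1.81-fold (log2 standard error 0.0787) and 1.78-fold (0.0650), and the receptor gene Tgfbr2 rose from 448 ± 18.5 to 685 ± 14.9 CPM (SD, n = 3 each). The camera adjusted p was 5.75e-07, and the adjusted p was 0.141 with an estimated correlation. In the NF-kB response list 10 of 22 tested members rose and 0 fell (11 and 0 when adjusted over the list alone). Bcl3, Nfkb1 at 1.45-fold, Rela at 1.45-fold and Tnfaip3, a feedback inhibitor, at 1.36-fold had the smallest p-values. This list had a camera adjusted p of 0.00181 (adjusted p = 0.201 with an estimated correlation).

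Immediate early genes and heat shock genes, which respond within minutes to stimulation or stress, also during tissue handling, were higher in mLN as lists. Fos rose 1.98-fold, Jun 1.91-fold, Egr1 1.83-fold and Zfp36 1.51-fold, and in all 8 of 18 tested immediate early members rose and 2 fell (9 and 2 when adjusted over the list alone; camera adjusted p = 1.97e-04; adjusted p = 0.396 with an estimated correlation). The chaperone genes Hsph1 and Hsp90ab1 rose 1.70-fold and 1.60-fold and the co-chaperone gene Stip1 1.40-fold. Of 14 heat shock members, 5 rose and 2 fell (7 and 2 when adjusted over the list alone; camera adjusted p = 0.00117; adjusted p = 0.142 with an estimated correlation). Among 23 genes that respond to the T cell receptor, 8 rose and 1 fell (9 and 1 when adjusted over the list alone), with Myc at 1.66-fold, Nr4a1 at 1.42-fold and Dusp2 at 1.28-fold among those higher and Tagap lower at 0.694 of its spleen level. That list did not pass the camera test (adjusted p = 0.146; 0.0442 without a filter on low counts). Its members gave 9 higher and 0 lower on log2 TPM and 3 and 1 on median-centred log2 TPM, where the list median went from 0.23 to 0.09.

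The interferon lists differed in direction. Of 51 type I interferon genes, 17 rose and 6 fell (18 and 6 when adjusted over the list alone), with the antiviral oligoadenylate synthetase genes Oas2 at 2.18-fold and Oas3 at 1.90-fold, Parp14 at 1.38-fold, and Slfn1 lower at 0.708 of its spleen level. The camera adjusted p was 0.0122, and the adjusted p was 0.355 with an estimated correlation. With the length trend removed the log2 fold changes of Oas2, Oas3, Parp14 and Slfn1 were 1.08, 0.82, 0.23 and -0.43. Of 26 type II interferon genes, 13 fell and 4 rose (14 and 4 when adjusted over the list alone; camera adjusted p = 0.0169; adjusted p = 0.192 with an estimated correlation), whereas 2 fell and 5 rose on log2 TPM, where the list median turned from -0.22 to 0.06. On median-centred log2 TPM 5 fell and 0 rose, and the median was -0.19. Igtp and Tgtp2, members of the immunity-related GTPase family, were at 0.668 and 0.723 of their spleen levels, and Tgtp2 shares reads with near-identical family members. Tapbp, which helps load peptides on MHC class I, and Nlrc5, an activator of MHC class I genes, rose 1.45-fold and 1.29-fold.

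Genes that mark naive T cells did not move as a group. Of 22 members of the naive and quiescence list, 6 rose and 9 fell (6 and 9 when adjusted over the list alone; camera adjusted p = 0.50), against 11 and 4 on log2 TPM and 5 and 9 on median-centred log2 TPM. The list median was 0.03 and the mean -0.04. Igfbp4 rose from 849 ± 73.5 to 1534 ± 123 CPM (SD, n = 3 each), while Il7r and Slfn2 fell, Slfn2 to 0.642 of its spleen level. Cd4 transcripts were at 930 ± 45.1 CPM in spleen and 891 ± 12.4 CPM in mLN (SD, n = 3 each; log2 fold change -0.06 with a standard error of 0.05, adjusted p = 0.433), a difference that turned to 0.25 on log2 TPM (adjusted p = 0.0225). Cd5, whose level follows the strength of self-recognition, had a log2 fold change of 0.08 with a standard error of 0.06 (adjusted p = 0.331; 0.00617 on log2 TPM). Within the T cell identity list 9 of 21 members fell and 4 rose (the same when adjusted over the list alone; camera adjusted p = 0.0899), against 4 and 11 on log2 TPM, where the list median turned from -0.06 to 0.25. On median-centred log2 TPM 8 fell and 6 rose, with a median of 0.0030. The list passed without spleen replicate 1 (adjusted p = 0.0322) or mLN replicate 3 (adjusted p = 0.0290). It also passed with upper-quartile factors (0.0327), with the GC trend removed (0.0351), and without mitochondrial, rRNA and ribosomal protein genes (0.0484). With the length trend removed 7 members rose and 7 fell, the median was -0.01 and the adjusted p was 0.80. Its lower members included the receptor components Cd3d, Cd3g, Cd247 and Trbc2, which were at 0.701, 0.696, 0.698 and 0.719 of their spleen levels. With the length trend removed their log2 fold changes moved from -0.51, -0.52, -0.52 and -0.48 to -0.39, -0.30, -0.41 and -0.15.

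The list of memory and effector T cell genes was lower in mLN by camera. Of 21 tested members 7 fell, 0 rose and 14 did not pass the test (8 fell and 0 rose when adjusted over the list alone), with S100a10 at 0.533, Lgals1 at 0.577, S100a11 at 0.584 and Crip1 at 0.686 of their spleen levels. The camera adjusted p was 0.00126, and the adjusted p was 0.105 with an estimated correlation. On log2 TPM 2 rose and 6 fell, and the list median went from -0.50 to -0.09; with the values centred 0 rose and 6 fell, with a median of -0.33. S100a10, S100a11 and Lgals1 are also expressed by myeloid cells, and in the same libraries all 11 neutrophil genes and 18 of 21 monocyte and macrophage genes fell. Crip1, S100a11 and Ly6a lost their calls after removal of the trend with transcript length. Cd44, a surface marker of antigen-experienced cells, was at 0.781 of its spleen level (adjusted p = 0.0387; 0.0694 by DESeq2; 0.122 with the GC trend removed), and its call was lost without spleen replicate 1 or 2 or without any mLN replicate, with adjusted p-values from 0.0609 to 0.175. Ly6c1 fell to 0.580 and Ly6a to 0.759 of their spleen levels, and 3 of the 7 tested Ly6 genes fell and 0 rose (3 and 0 when adjusted over the list alone; list adjusted p = 0.0853; 0.0458 without mLN replicate 3), against 1 and 1 both on log2 TPM and with the length trend removed, and 2 and 0 on median-centred log2 TPM.

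Genes of migration went both ways, with 8 of 30 higher and 10 lower (9 and 11 when adjusted over the list alone; list adjusted p = 0.434), against 13 and 4 on log2 TPM, where the list median turned from -0.04 to 0.24. With the TPM values centred, 6 were higher and 7 lower, with a median of -0.01. P2ry10, a lipid receptor gene, fell to 0.542 of its spleen level, while Dock8, which supports migration through tissue, rose 1.41-fold. With the length trend removed the log2 fold changes of P2ry10 and Dock8 were -0.90 and 0.26 (adjusted p = 2.87e-07 and 0.00105, edgeR). In the list of retinoic acid and gut homing genes 4 of 14 rose and 0 fell (4 and 1 when adjusted over the list alone; list adjusted p = 0.362). The integrin subunit gene Itgb7 rose from 665 ± 49.7 to 895 ± 45.5 CPM (SD, n = 3 each), the retinoic acid receptor gene Rara rose 1.66-fold, and P2rx7 rose 1.48-fold. Of the lineage factor list, 2 of 7 members rose, Runx3 at 1.56-fold and Gata3 at 1.39-fold, and 2 fell, among them Stat4 at 0.777 of its spleen level (3 and 2 when adjusted over the list alone; list adjusted p = 0.434).

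Transcripts of the protein synthesis and respiratory machinery took a smaller part of the mLN libraries. Ribosomal protein genes made up 11.7 ± 0.10% of the counts in spleen and 8.39 ± 0.419% in mLN (SD, n = 3 each), and 79 of 86 tested members fell and 0 rose (81 and 0 when adjusted over the list alone), Rpl31 to 0.608 of its spleen level. The camera adjusted p was 5.05e-62, and the adjusted p was 0.105 with an estimated correlation. Genes of the mitochondrial genome made up 3.96 ± 0.228% and 2.31 ± 0.164% of the counts, respectively. Of the 13 mitochondrial messenger RNAs, 10 fell and 0 rose (12 and 0 when adjusted over the list alone; camera adjusted p = 2.66e-22; adjusted p = 0.0684 with an estimated correlation), with mt-Co2 at 0.558 and mt-Nd5 at 0.579 of their spleen levels. Of 75 nuclear oxidative phosphorylation genes, 44 fell and 2 rose (53 and 2 when adjusted over the list alone; camera adjusted p = 4.71e-12; adjusted p = 0.141 with an estimated correlation), against 6 and 3 on log2 TPM and 31 and 0 on median-centred log2 TPM, where the list median was -0.34. Ndufa9 was at 0.657 and Uqcrc2 at 0.701 of its spleen level.

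These groups consist largely of short transcripts, and the fold changes followed transcript length. Across the 12486 tested genes, which are not independent replicates, Spearman's rho between the log2 fold change and the length was 0.370. Of 1421 genes with transcripts up to 1000 nt, 423 fell and 11 rose, and of 607 genes above 6000 nt, 277 rose and 16 fell. After removal of this trend, 55 ribosomal protein genes were lower and 2 higher, the oxidative phosphorylation list had 8 lower and 3 higher members, and 9 mitochondrial messenger RNAs were lower. Segments of the variable part of the T cell receptor, which are short, fell in 11 of 89 cases and rose in 0 (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0314; adjusted p = 0.464 with an estimated correlation), while the list median turned from -0.34 to 0.08 on log2 TPM. With the TPM values centred it was -0.16, with 10 members lower and 0 higher. With the trend removed 0 fell, the list median was 0.09 and the adjusted p was 0.80. The call of this list was also lost without spleen replicate 2 (adjusted p = 0.0690) or mLN replicate 2 (adjusted p = 0.127), without a filter on low counts (0.0511) and with upper-quartile factors (0.0903).

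**Figure D2:**
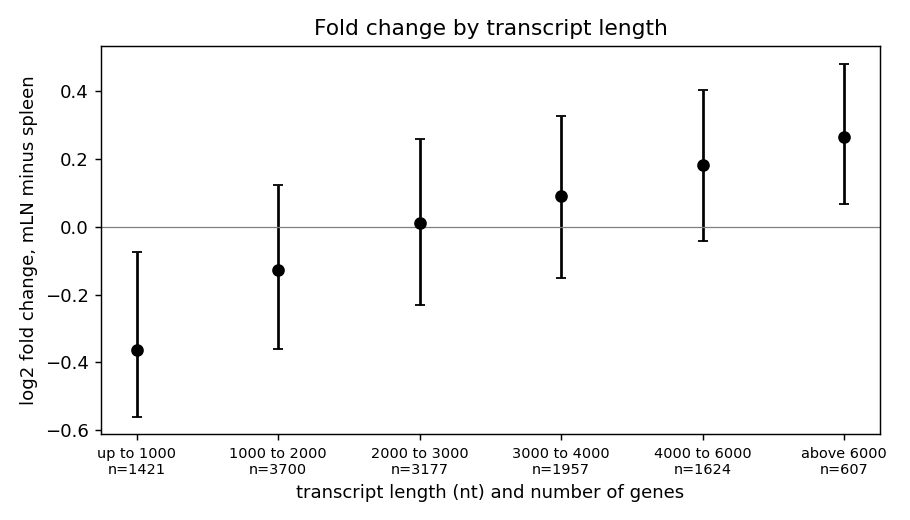
Log2 fold change, mLN minus spleen, of the tested genes by transcript length in nucleotides; points are medians over genes and bars span the lower to the upper quartile. The median went from -0.36 in the shortest class of 1421 genes to 0.26 in the longest class of 607 genes.

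Genes of cholesterol synthesis included strong decreases. Msmo1, Idi1 and Cyp51, enzymes of the pathway, were at 0.503, 0.525 and 0.599 of their spleen levels, while the cholesterol exporter gene Abcg1 rose 1.52-fold. Of 29 members 12 fell and 7 rose (13 and 7 when adjusted over the list alone), against 2 and 6 on log2 TPM and 7 and 3 on median-centred log2 TPM. The list adjusted p was 0.145, and 0.00468 after removal of the length trend. Of 27 glycolysis and hypoxia genes, 7 fell and 1, the hexokinase gene Hk1, rose 1.47-fold (7 and 1 when adjusted over the list alone; list adjusted p = 0.434), against 1 and 9 on log2 TPM and 2 and 1 on median-centred log2 TPM. The list median was 0.01 while the test pointed down. Pgk1 was at 0.737 of its spleen level. Of 26 cell cycle genes 3 fell and 0 rose (3 and 0 when adjusted over the list alone; list adjusted p = 0.350), namely Pcna, Stmn1 and Mcm7. On log2 TPM 1 fell and 1 rose, and on median-centred log2 TPM 3 fell and 0 rose. In the glucocorticoid list 3 of 14 rose and 4 fell, with Tsc22d3 at 0.697 of its spleen level (2 fell and 3 rose on log2 TPM, where the list median turned from -0.01 to 0.17, and 3 and 1 with a median of -0.08 on median-centred log2 TPM), and in the clock list 3 of 17 rose and 1 fell, with Csnk1d 1.35-fold higher (4 and 4, and 3 and 1, when adjusted over each list alone; list adjusted p = 0.394 and 0.441).

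**Figure D3:**
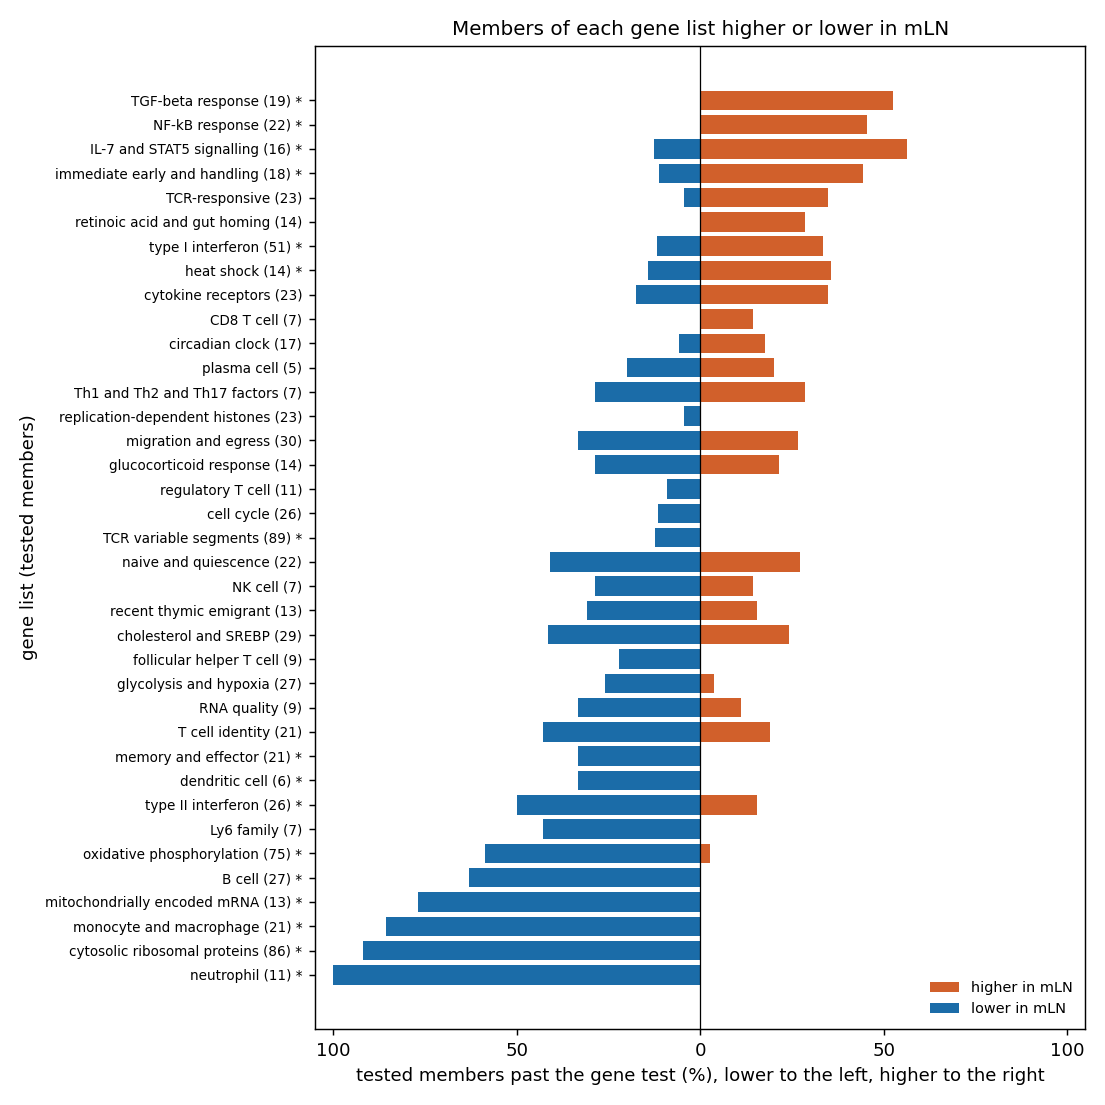
Percentage of the tested members of each of 37 gene lists that were higher (right) or lower (left) in mLN than in spleen by the gene test; the number of tested members is in parentheses and a star marks lists past the camera threshold with the preset correlation. All 11 neutrophil genes were lower, and 10 of 19 TGF-beta response genes were higher with 0 lower.

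Markers of other cell types were among the most strongly different transcripts. S100a9, a neutrophil protein gene, was at 11.6 ± 3.13 CPM in spleen and 0.169 ± 0.0874 CPM in mLN (SD, n = 3 each), Csf3r at 10.5 ± 0.746 and 0.116 ± 0.200 CPM (0, 0 and 7 counts in mLN replicates 1, 2 and 3), and all 11 tested neutrophil genes fell (camera adjusted p = 4.55e-24; adjusted p = 0.0152 with an estimated correlation). Of 21 monocyte and macrophage genes 18 fell and 0 rose, Lyz2 from 18.2 ± 0.570 to 1.84 ± 0.679 CPM and Mpeg1 from 12.9 ± 2.26 to 0.774 ± 0.479 CPM (camera adjusted p = 1.16e-15; adjusted p = 0.0301 with an estimated correlation). Of 27 B cell genes 17 fell and 0 rose, including Igkc at 0.131 and the MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 at 0.234, 0.193, 0.252 and 0.196 of their spleen levels (camera adjusted p = 1.16e-15; adjusted p = 0.0542 with an estimated correlation). Of 6 dendritic cell genes 2 fell, with Itgax at 0.0630 of its spleen level (camera adjusted p = 0.0350; adjusted p = 0.201 with an estimated correlation; 0.0723 by limma-voom). The size of the Itgax difference rests on few counts, 1, 8 and 1 in mLN replicates 1, 2 and 3, and its log2 fold change of -3.99 became -5.82 without mLN replicate 2. Adjusted over the list alone, 11 neutrophil, 18 monocyte and macrophage, 18 B cell and 2 dendritic cell genes fell.

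Among the genes lower by at least 2-fold, 185 of 197 had a spleen mean under 20 CPM and 131 had an mLN mean under 1 CPM. Gpr34 was at 0.368 and Myo6 at 0.386 of their spleen levels. A second gene identifier named Zc3h11a, which shares its symbol and possibly its reads with the main Zc3h11a gene, was at 0.415 of its spleen level, and its call was lost without spleen replicate 3 (adjusted p = 0.0591) or mLN replicate 3 (adjusted p = 0.113). Lists of other T cell states and lineages did not pass the camera test, with list adjusted p-values of 0.524 for regulatory T cells, 0.350 for follicular helper T cells, 0.431 for recent thymic emigrants, 0.434 for CD8 T cells, 0.145 for NK cells, 0.50 for plasma cells, 0.145 for RNA quality and 0.50 for replication-dependent histones. In these lists 0 rose and 1 fell of 11 regulatory, 0 and 2 of 9 follicular helper, 2 and 4 of 13 recent emigrant, 1 and 0 of 7 CD8, 1 and 2 of 7 NK, 1 and 1 of 5 plasma cell, 1 and 3 of 9 RNA quality and 0 and 1 of 23 histone genes; adjusted over the list alone, the counts were 0 and 0, 0 and 1, 2 and 4, 1 and 0, 1 and 3, 1 and 1, 1 and 4, and 0 and 0. Lists too short for the test had 0 of 3 gamma delta and NKT, 0 of 4 red blood cell, 1 of 4 platelet, 1 of 1 stroma, 1 of 2 epithelium, 1 of 4 sex-linked and 3 of 3 immunoglobulin segment genes called. Cd8a was at 1.92 ± 0.480 and 3.83 ± 1.73 CPM in spleen and mLN (SD, n = 3 each; adjusted p = 0.0778), and it was called higher in mLN without mLN replicate 2 (log2 fold change 1.31, adjusted p = 0.0193) and with the GC trend removed (adjusted p = 0.0397). Foxp3 was at 1.55 ± 0.432 and 0.785 ± 0.166 CPM (SD, n = 3 each; adjusted p = 0.225). Hbb-bs, a red cell gene, had at most 4 counts in any library. Xist, expressed in female cells, had at most 14 counts, and the Y-linked gene Ddx3y was at 234 and 242 CPM in spleen and mLN (adjusted p = 0.684; 0.0448 on log2 TPM and 1.49e-04 with the GC trend removed, higher in mLN in both).

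The first principal component of the log2 CPM values held 42.3% of the variance and separated the tissues. In 2680 genes all 3 mLN values lay above the 3 spleen values and in 2539 all lay below, a separation that chance gives in 10% of genes. At an unadjusted p under 0.05 there were 4891 genes. Of the 37 lists tested, 16 passed the camera threshold with the preset correlation of 0.01, and 2, neutrophil and monocyte and macrophage, passed with an estimated correlation. Among lists higher in mLN, log2 TPM gave 24 members higher and 0 lower for type I interferon, 10 and 0 for heat shock, 11 and 0 for immediate early, 10 and 0 for TGF-beta, 13 and 0 for NF-kB and 12 and 1 for IL-7 and STAT5. The same counts on median-centred log2 TPM were 10 and 4, 4 and 0, 7 and 1, 6 and 0, 5 and 0, and 5 and 1. On the same 2 scales the cytokine receptor list had 12 higher and 2 lower and then 5 and 3, the retinoic acid and gut homing list 5 and 0 and then 2 and 1, and the lineage factor list 3 and 0 and then 1 and 1. The clock list had 4 and 0 and then 1 and 0, where its median turned from 0.04 to -0.16. For ribosomal proteins 1 was higher and 58 lower and then 0 and 77. With the GC trend removed the type I interferon list had 30 higher and 4 lower and the heat shock list 10 and 1. On log2 TPM the calls of Slfn1, Pgk1, Stat4, Stmn1, Mcm7, Tagap, Cyp51, Gpr34, Uqcrc2, Ly6a and Cd44 were lost, and on median-centred log2 TPM those of Abcg1, Gata3, Nr4a1, Nlrc5, Tapbp, P2rx7, Il2rg and Cd44.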

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

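The tests chosen after seeing the data were the length and GC corrections, the omission of gene families or of markers of other cell types, and median-centred TPM. No gene called on counts was called in the opposite direction under any of the 20 alternatives. Leaving out each library gave 1500 to 1970 genes higher, 1324 to 1710 lower and 15 to 19 lists. The count of lower genes was 1069 at an adjusted p under 0.01, where the stricter threshold is the reason, and 385 on log2 TPM, where the median of all genes is shifted. On median-centred log2 TPM there were 805 higher and 960 lower; the cause was not tested. Removing the length trend gave 1792 higher and 1148 lower, of which 1535 and 976 were also called without it, and removing the GC trend gave 2636 and 1470, 64.2% of them higher. The list count of 16 became 2 with an estimated correlation and 27 with fry, which does not compare a list with other genes. On log2 TPM the log2 fold changes of Il2rg, Neat1, Gapdh, Pecam1 and Cd4 turned to 0.00164, 0.0851, 0.0718, 0.0618 and 0.25. On median-centred log2 TPM they were -0.24, -0.16, -0.17, -0.18 and 0.0030; the cause was not tested. With the length trend removed the median of the TCR variable segments turned to 0.0925. Of the 143 named genes called, 16 lost their call without at least 1 library, as did 1 of the 16 lists.

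With the replicate number as a block there were 2566 genes higher, 2140 lower and 13 lists, against 2010, 1689 and 16 without it. The type I interferon, dendritic cell and TCR variable segment lists had adjusted p-values of 0.0552, 0.0870 and 0.0520. Of the genes named by the rule, Xntrpc and the second Zc3h11a identifier lost their calls (adjusted p = 0.216 and 0.135, edgeR). Bcl6, Hist1h1c, Itgb3, Ly6e and Mcm2 gained one. Residuals of same-numbered libraries correlated at 0.0223, 0.00230 and 0.0652, all positive but small. These correlations show no clear pairing, although the block gave more gene calls. Correlations this small, with 3 libraries per tissue, cannot exclude that a number marks a shared animal or day. Not every library correlated best with its own number: mLN replicate 1 was highest with spleen replicate 2, at 0.0238, and mLN replicate 2 with spleen replicate 1, at 0.0147.

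Depth limits what can be said of the weakest markers, since 123 of the 130 genes lower by at least 4-fold had an mLN mean under 1 CPM. In the dendritic cell list 1 member, Flt3, had 0 counts in every mLN library. The list median of -0.58 was the same with Flt3 at its bound of 3 counts over the group. But a median hardly responds to 1 extreme member, so this says nothing about the effect of depth.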

Other observations

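Tests chosen only after the result was seen are those reported here on fragment length, abundant gene families, RNAs without a poly(A) tail, ribosomal and respiratory genes, markers of other cells, the length correction of lists, handling, STAT3, nucleolar genes and FOXO targets. The tests on fragment length, respiratory genes, STAT3, nucleolar genes and FOXO targets were also revised after first values had been seen. The genes in the next paragraph were likewise named after their values were seen.

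Outside the fixed lists, Tcof1, Urb1, Nol6, Mybbp1a and Pprc1, which act in or on the making of ribosomes and mitochondria, had log2 fold changes of 0.76, 0.77, 0.67, 0.65 and 0.81, while Npm1 was at -0.47. The receptor genes Notch1 and Notch2 and the Notch regulator Dtx1 were at 0.88, 0.66 and 0.85 (adjusted p = 6.66e-08, 1.93e-05 and 0.0277, edgeR); no list of Notch genes was tested. Stat3 rose (adjusted p = 7.01e-09, edgeR) from 214 ± 3.13 to 366 ± 7.40 CPM (SD, n = 3 each). A hypothesis of higher nucleolar activity was tested on a list of 40 nucleolar genes, which holds Npm1 and none of the 5 higher genes just named. Of the 40, 12 rose and 5, Npm1 included, fell. The list gave an adjusted p of 0.225, and with the length trend removed 0.0645 (0.217 with an estimated correlation), so the hypothesis did not pass the threshold and stays open. Sesn1 and Ccng2, which FOXO factors induce, fell, at -0.90 and -0.66, but 22 other FOXO targets went both ways. Of these 3 rose and 6 fell (camera adjusted p = 0.804, pointing up). With the length trend removed 2 rose and 7 fell (camera adjusted p = 0.343, pointing down), which decides nothing about FOXO activity.

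The broadest pattern was the rise of long and fall of short transcripts in mLN. Relative to the mean of all libraries, the slope of log2 CPM on log10 length was -0.27 ± 0.00514 in spleen and 0.27 ± 0.123 in mLN libraries (mean ± SD, n = 3 each); with fragment length in a linear model over the 6 libraries 84.8% of the difference remained, which argues against fragment size as the whole cause. Omitting mitochondrial, rRNA and ribosomal protein genes left rho at 0.360. But the same fold changes were used for 12383 of the 12486 genes, so rho could hardly change. This decides nothing about abundant families taking the counts. With the GC trend removed rho was 0.448, against 0.370 before, so GC content does not account for the length trend. The log2 fold change also followed transcript GC content itself, with a Spearman's rho of 0.295 over 12473 genes, and the cause of that trend was not tested. Less complete poly(A) selection in spleen may contribute. All 10 tested RNA genes taken by biotype as lacking a poly(A) tail had negative log2 fold changes, 8 of them called (median -0.66 with the length trend removed). The biotypes included mitochondrial rRNA, and mitochondrial messenger RNAs fell as well. But 23 replication-dependent histones, near the floor at a median of 2.03 CPM, had a median of 0.04 with the length trend removed. So this cannot be told apart from a tissue difference, which was not tested. RNA quality and preparation were not varied apart from the organ, so the cause of the length trend stays open. With the length trend removed 64.0% of ribosomal protein genes were lower and their median moved from -0.53 to -0.21. So the average length trend may account for part of their fall, and its removal left a smaller part. Whether that part is also linked to length was not tested. The median of -0.53 lay within the quartiles of all genes up to 1000 nt, -0.56 and -0.07. Of the oxidative phosphorylation genes 10.7% were lower with the length trend removed and the list median moved from -0.38 to -0.07, a part that stays open.

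Markers of myeloid and B cells were higher in the spleen libraries, which the length trend does not account for, since the neutrophil median was -4.92 after its removal. Carry-over of splenic neutrophils, macrophages and B cells is a candidate explanation that was not tested independently: 46 of 59 markers (78.0%) were higher in spleen and 0 in mLN, but this count restates the pattern. Of these 59, 9 had a mean of at least 10 CPM in the mLN libraries, and the sort that would remove such cells is not described in the labels. The most abundant markers moved less, Ighm from 487 to 339 CPM and Ctsd from 346 to 279 CPM, while Igkc went from 18.6 to 2.40 CPM. Outside these 59, Ighg1 of the plasma cell list and Cdh1 of the epithelium list were higher in mLN (adjusted p = 0.00221 and 0.0180, edgeR). Cdh1 was weakly expressed, with an mLN mean of 1.71 CPM, and the call of Ighg1 was lost on median-centred log2 TPM (adjusted p = 0.114, limma). A difference in the T cells themselves stays open, untested, for genes T cells also express, and so does carry-over for the S100a10, S100a11 and Lgals1 genes of the memory list, which myeloid cells also express.

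Immediate early, heat shock, TGF-beta, NF-kB and STAT5 lists were higher in mLN by camera at the preset correlation, but with an estimated correlation their adjusted p-values were 0.396, 0.142, 0.141, 0.201 and 0.105. At the preset correlation the length trend does not account for it, since all 5 lists had an adjusted p of at most 0.00252 with it removed, while the STAT5 list had 0.0683 with the GC trend removed, where its median moved from 0.24 to 0.20. Longer or warmer handling of mLN cells may raise such genes. Of the tested immediate early genes 44.4% rose, and the list median was 0.52. Among those not called, Dusp1 was at 0.06 and Junb at 0.86 (adjusted p = 0.780 and 0.0605, edgeR). Since the labels do not describe the processing of either organ, handling cannot be told apart from tissue. STAT3 signalling is a hypothesis prompted by Socs3, Stat3 and Bcl3. On counts 23 other targets gave 11 rises and 1 fall (camera adjusted p = 2.31e-05). With the length trend removed these targets gave 12 and 1 (camera adjusted p = 9.84e-06, and 0.191 with an estimated correlation). But most of these belong to the fixed lists and some had been seen. The 5 targets outside the fixed lists gave an adjusted p of 0.0823 with the length trend removed. These 4 lists (STAT3 targets, the 5 outside, nucleolar, FOXO) were adjusted together.

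The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3699 genes and the highest other split 1, and only the real split itself reached that count. Every other split mixes the tissues, which adds the tissue difference to the spread within groups, so few gene calls were bound to result. For lists, the real split gave 16 and the others between 4 and 13. The list test at the preset correlation thus called lists in splits with almost no called genes.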
